A study of Homo sapiens with 12 samples.

How the data were processed

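RNA was measured by RNA sequencing in HepG2 cells, an established line from a human hepatocellular carcinoma that keeps many hepatocyte functions. The 12 libraries fall into 4 groups of 3: cells with 0.1% DMSO (the vehicle control), cells with 200 µM MEHP (mono(2-ethylhexyl) phthalate, a breakdown product of a common phthalate plasticiser), cells with 200 µM MEHP and M1 macrophages, and cells with 200 µM MEHP and M2 macrophages. Macrophages were added at 30000 cells per well and exposure to MEHP lasted 24 h, per the labels' protocols. The labels give no duration for the DMSO group, so a difference in time between it and the MEHP groups is not excluded. M1 and M2 are the names in use for inflammatory and alternatively activated macrophages. The labels do not say whether the macrophages touched the HepG2 cells or were kept apart, nor where they came from, and there was no group with macrophages and no MEHP. RNA was taken with a phenol reagent and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

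The values are FPKM (fragments per kilobase of gene length, scaled to a fixed number of fragments per library), deposited by the authors as 1 table of 58735 genes with gene names, positions and lengths, per the file headers. StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 and the build hg38/GRCh38 are named per the submitters' processing notes, without their roles. The aligner, the annotation release and the use of strand are not given in the sources used here. All 58735 gene identifiers were found in GENCODE 29 (Ensembl 94, GRCh38), where 99.98% had the same start and end and 100% the same name. Coordinates are those of the deposited table. Without a stated use of strand, genes that overlap another gene, and genes with close copies, are uncertain in level.

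In each library, FPKM times gene length was a whole multiple of 1 step for 100% of the values above 0 (tolerance 0.01 of a read), so whole reads per gene could be worked out. The recovered totals were 17533504 to 20889986 reads per library. The authors' denominators were proportional to median-of-ratios size factors rather than to these totals, so the deposited FPKM already carry a scaling between libraries. No 2 libraries of a group were identical, and all pairs differed by more than sampling noise in a chi-square comparison of reads over genes.

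The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), the scale computed here from the deposited FPKM. It covered 12171 genes with a mean of at least 1 FPKM over the 12 libraries, 10215 of them protein-coding. One 4-group model gave all 6 comparisons, with moderated variances that follow a trend on mean expression. P-values were adjusted within a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are differences on the log2(FPKM + 1) scale and understate the change of genes near or under 1 FPKM. Values are given as mean ± SD with n = 3, and fold changes with their standard error (SE).

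Of 47 gene lists fixed beforehand, the 40 with at least 5 tested members entered limma's camera test with a preset correlation between genes of 0.01, adjusted over 160 tests in the 4 main comparisons. Camera with an estimated correlation was run beside it, and calls lost there are named. Counts of list members were made over all tested genes and also adjusted over the list alone. The 7 lists with too few tested members were MHC class II, macrophage and leukocyte, M1, M2, lymphocyte, fibroblast and endothelial markers. For these, reads of members nearly absent from the control were counted.

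Named genes followed a rule fixed beforehand. In each main comparison it took the 6 largest increases and 6 largest decreases among called protein-coding genes whose groups did not overlap. It added the 3 members with the smallest p in the list's direction from each of the 6 lists with the smallest adjusted p. It also took the 2 members with the smallest p of the lists of PPAR-alpha targets, acute phase proteins, leukocyte markers and interferon-stimulated genes. Some genes that met the rule are not reported here. Other called members of the fixed lists are named as examples chosen after their values were seen.

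The fit was tested on simulated data for the comparison of MEHP with DMSO over 12171 genes, 200 of them changed. It recovered 91% of the 2-fold and 63% of the 1.5-fold changes and called 5 unchanged genes. The simulation gave all genes and libraries the same spread beyond read sampling and held no outlying libraries. Recovery in the real data may therefore be lower. None of 30 random lists reached p under 0.05, but genes were simulated independently, so the preset correlation was not tested by them. Other splits of the real libraries called up to 12 lists for MEHP against DMSO and 16 for M1 against MEHP. They called up to 8 for M2 against MEHP and 10 for M1 against M2. Each of those splits mixes both groups unevenly and so keeps part of any real difference. These counts therefore cannot show whether list p-values with the preset correlation are too small, which stays possible. Alternatives were another pseudocount (0.1), weaker filters, other scalings, the 6 libraries of a comparison alone, a replicate block, a 2-fold limit, limma voom on recovered reads, and leaving out each library. Added after the data were seen were a fit without 3 libraries that lay apart from their groups, and a fit with a smooth trend on gene length and GC content removed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for reading and counting, with matplotlib 3.10.9 for figures.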

Results

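Messenger RNA was profiled in HepG2 hepatocellular carcinoma cells under 4 conditions with 3 libraries each: DMSO vehicle (0.1%), MEHP (200 µM, a phthalate plasticiser metabolite), MEHP with M1 macrophages, and MEHP with M2 macrophages (30000 macrophages per well, 24 h). The libraries held 17533504 to 20889986 reads assigned to genes, and the test covered 12171 genes. The comparisons answer what MEHP alone changed against the vehicle, what each macrophage type changed at the same MEHP dose, and where the macrophage types differed. Since no group had macrophages without MEHP, the effect of macrophages alone was not measured.

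Most of the variance between libraries lay on 2 principal components (43.2% and 18.6%). DMSO and MEHP libraries lay on one side of the second component and 5 of the 6 co-culture libraries on the other. MEHP replicate 2, M1 replicate 3 and M2 replicate 2 lay apart from the other libraries of their groups along the first component. In these 3 libraries ribosomal protein genes took 7.22%, 6.96% and 8.57% of the reads, against 5.96% to 6.58% in the other 9, and mitochondrially encoded proteins took 4.57%, 4.40% and 4.84%, against 3.38% to 4.01%. Each main count is therefore also given without these 3 libraries, a choice made after seeing the data. The share of reads from mitochondrial ribosomal RNA moved with the groups. It was 0.72% to 0.79% with DMSO, 0.83% to 1.03% with MEHP, 1.02% to 1.20% with M1 and 1.13% to 1.67% with M2 macrophages. Protein-coding genes took 97.25% to 97.38%, 96.88% to 97.27%, 96.78% to 97.00% and 96.05% to 96.83% in the same order. The cause of these shifts was not tested.

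**Figure D1:**
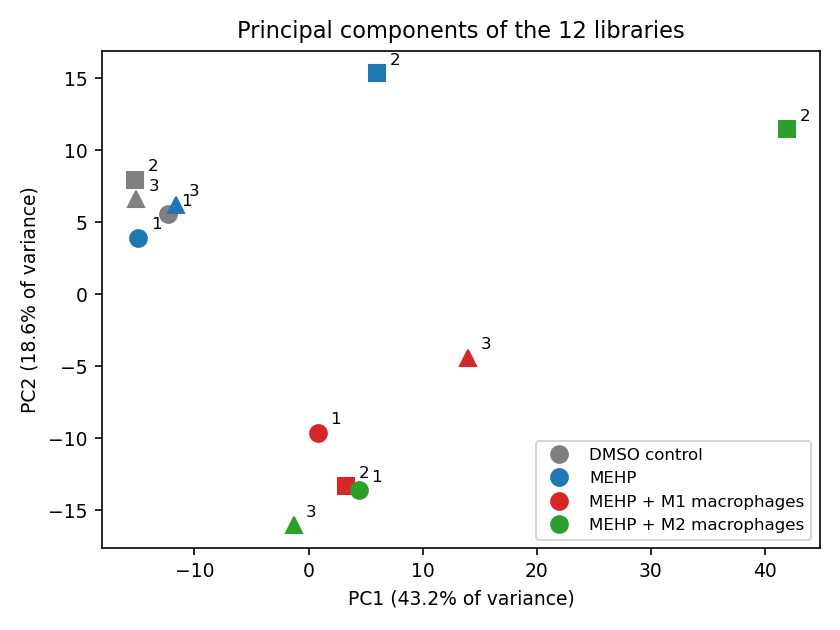
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library coloured by group, numbered by replicate, and the share of variance in percent on each axis. M2 replicate 2 lies farthest out on the first component (41.94), MEHP replicate 2 has the highest value on the second (15.34), and the DMSO libraries lie close together.

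MEHP alone raised a small set of genes of fatty acid handling and sterol synthesis and lowered fibrinogen genes. CREB3L3, a liver-enriched transcription factor of lipid metabolism genes (chromosome 19, 4153601 to 4173054, GRCh38, ENSG00000060566), rose from 3.31 ± 0.212 to 12.4 ± 1.42 FPKM (SD, n = 3). PLIN2, a coat protein of lipid droplets (chromosome 9, 19108375 to 19149290, ENSG00000147872), rose from 54.2 ± 2.97 to 126 ± 5.24 FPKM. CPT1A, which commits fatty acids to mitochondrial oxidation, rose from 12.3 ± 0.271 to 23.1 ± 1.76 FPKM, and SLC25A20, the carnitine-acylcarnitine carrier of the mitochondrial membrane, from 5.83 ± 0.208 to 11.1 ± 0.654 FPKM. FGA and FGB, which encode fibrinogen chains in a cluster on chromosome 4, fell from 314 ± 9.86 to 226 ± 13 and from 85.4 ± 1.47 to 61.3 ± 4.79 FPKM.

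These were among 11 genes called by limma (adjusted p under the 0.05 threshold after Benjamini-Hochberg adjustment), 9 higher and 2 lower. The log2 fold changes were 1.63 ± 0.17 (SE) for CREB3L3 (limma adjusted p = 0.00336), 1.20 ± 0.11 for PLIN2 (limma adjusted p = 0.00124), 0.86 ± 0.07 for CPT1A and 0.82 ± 0.06 for SLC25A20 (limma adjusted p = 0.000792 for both). SGK2, a kinase of the serum and glucocorticoid-regulated family, rose by 0.63. ACSS2, which makes acetyl-CoA from acetate and overlaps GGT7 on the other strand, rose by 0.51. FADS2, a fatty acid desaturase that overlaps FADS1 on the other strand and is named outside the rule to complete the 11, rose by 0.37. All 11 had every MEHP library on 1 side of every DMSO library, which held for 14.9% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 440 genes.

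Of 24 measured PPAR-alpha targets, 5 rose (SLC25A20, CPT1A, PLIN2, CREB3L3 and FADS2) and 19 were not called. Adjusted over the list alone, 10 were higher and 1 lower, and the list stood above other genes (median log2 0.21, camera adjusted p = 4.0e-18; adjusted p = 0.00094 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake, 2 rose, DHCR7 (the enzyme of the last step of cholesterol synthesis, 33.6 ± 0.829 to 47.4 ± 0.225 FPKM) and FDFT1 (squalene synthase, 58.1 ± 0.695 to 78.9 ± 1.52 FPKM). Adjusted over the list alone, 11 cholesterol genes were higher and 0 lower (median log2 0.27, camera adjusted p = 5.5e-25; adjusted p = 0.0050 with an estimated correlation). LSS, lanosterol synthase, went from 30.8 to 43.3 FPKM without passing the main test (limma adjusted p = 0.055). It was called with median-ratio scaling (0.48), with its 6 libraries alone (0.48), with voom (0.49), without the 3 libraries that lay apart (0.51) and without M2 replicate 1 or 2 (0.48 in each). Among 15 fatty acid synthesis genes 1 rose, ACSS2, and 3 were higher when adjusted over the list alone (median log2 0.16, camera adjusted p = 1.4e-08; adjusted p = 0.0059 with an estimated correlation). FASN, fatty acid synthase, was at 177 FPKM in DMSO and 213 FPKM in MEHP (limma adjusted p = 0.311). The 28 NRF2 targets, genes of the oxidative and electrophile defence, stood higher as a list with 0 members called (2 higher adjusted over the list alone, median log2 0.10, camera adjusted p = 7.7e-09; adjusted p = 0.033 with an estimated correlation). AKR1B10 and AKR1C1, aldo-keto reductases with close paralogs, were at 122 and 85.1 FPKM in MEHP against 97.4 and 61.5 FPKM in DMSO, and HMOX1, heme oxygenase, at 41.5 against 32.7 FPKM. None of these 3 passed the main test alone. AKR1B10 was called without the 3 libraries that lay apart (0.35) and, like HMOX1, with the length and GC trend removed (0.31 and 0.29). AKR1B10 was also called without M2 replicate 2 (0.33).

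Of 16 acute phase genes, 2 fell, the fibrinogen genes FGA and FGB, and 14 were not called. Adjusted over the list alone, 3 were lower, the 3rd being the neighbouring FGG, at 246 ± 5.65 FPKM in DMSO and 170 ± 7.11 in MEHP (limma adjusted p = 0.0705 over all genes, called with its 6 libraries alone at -0.53, without the 3 libraries that lay apart at -0.55, with the length and GC trend removed at -0.51 and without M2 replicate 2 at -0.53). The list stood lower (median log2 -0.07, camera adjusted p = 9.9e-06, adjusted p = 0.038 with an estimated correlation), and its called members are fibrinogen genes only. The 32 G2/M genes stood slightly lower as a list (median log2 -0.11, camera adjusted p = 1.2e-06; adjusted p = 0.10 with an estimated correlation), with 0 called and 0 called when adjusted over the list alone. The 22 interferon-stimulated genes had 0 called members and the list was not called (camera adjusted p = 0.28). In all, 12 of 40 lists were called and 5 of them also with an estimated correlation: PPAR-alpha targets, cholesterol synthesis, fatty acid synthesis, NRF2 targets and acute phase proteins.

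The count of 11 genes changed with each of the 6 libraries, being 4 without DMSO replicate 1 or 2, 7 without DMSO replicate 3, 6 without MEHP replicate 1, 7 without MEHP replicate 2 and 4 without MEHP replicate 3. CREB3L3, PLIN2, CPT1A and SLC25A20 stayed called each time, while DHCR7 (0.47 to 0.50), FDFT1 (0.42 to 0.44) and FADS2 (0.35 to 0.39) lost their calls each time with little change in fold. With the 6 libraries of this comparison alone FADS2 (0.37) and FGB (-0.47) were not called, and with quantile normalization FDFT1 (0.45) and FGA (-0.52) were not. Libraries outside the comparison enter only the shared variance, yet the count was 29 without M2 replicate 2 and 9 to 13 without any 1 of the other 5. FADS2 was not called without any 1 of the M1 libraries or M2 replicate 1 (0.37 in each), nor FDFT1 without M1 replicate 3 (0.44). SGK2 lost its call without DMSO replicate 1 (0.60) or 2 (0.62) or MEHP replicate 2 (0.60) or 3 (0.63), and ACSS2 without DMSO replicate 1 (0.50) or 2 (0.51) or MEHP replicate 1 (0.51) or 3 (0.51). FGA and FGB stayed called only without MEHP replicate 2, losing their calls without DMSO replicate 1 (-0.45 and -0.47), 2 (-0.49 and -0.47) or 3 (-0.48 and -0.49) or MEHP replicate 1 (-0.47 and -0.46) or 3 (-0.43 and -0.43). Without the 3 libraries that lay apart 32 genes were called, all 11 among them, and 28 (19 higher, 9 lower) after the length and GC trend was removed.

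**Figure D2:**
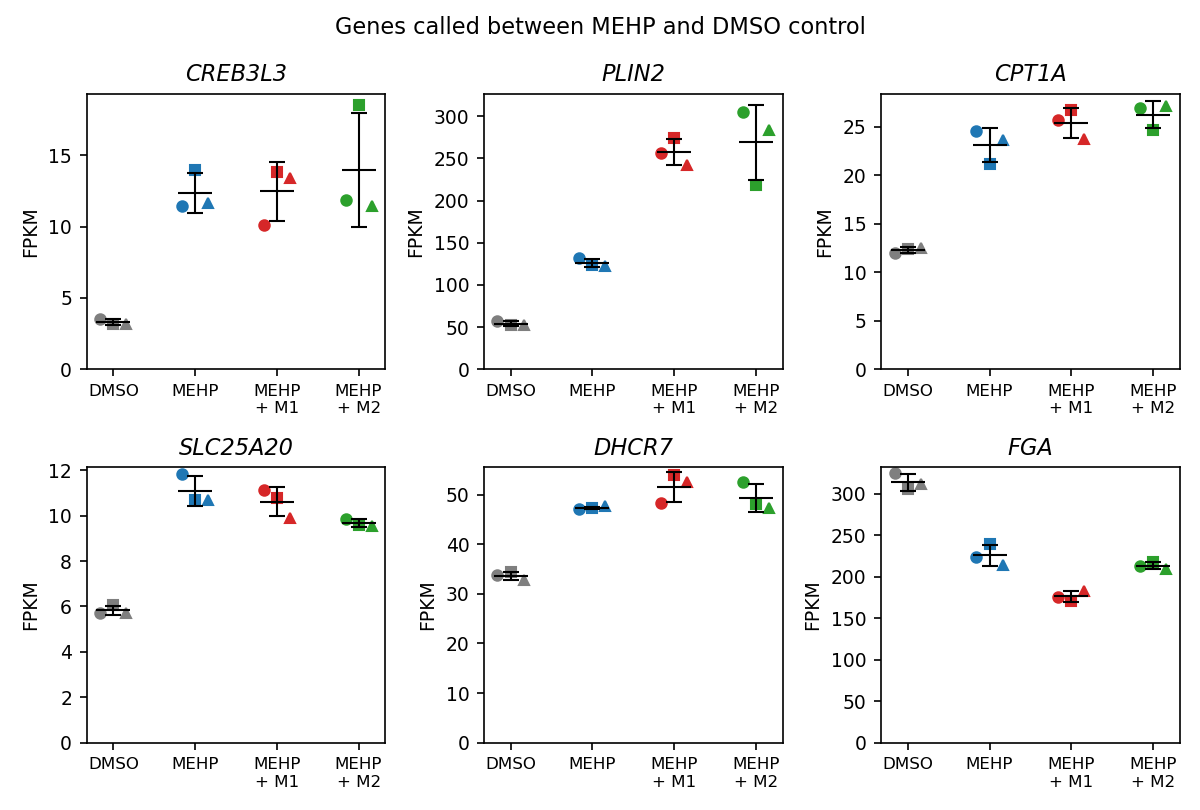
FPKM (vertical axis, linear from 0) of 6 genes called between MEHP and DMSO, with 1 point per library in each of the 4 groups (horizontal axis) and black bars for the mean and SD of 3 libraries. CREB3L3 stands at 3.31 in DMSO and 12.4 to 13.9 in the 3 groups with MEHP, PLIN2 at 54.2 in DMSO, 126 with MEHP and 257 to 269 with macrophages, and FGA at 314 in DMSO and 176 to 226 in the others.

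With M1 macrophages at the same MEHP dose, HepG2 libraries showed a strong rise of interferon-stimulated, antigen presentation and NF-kB genes together with hypoxia and glycolysis genes. IFI6, an interferon-induced gene (chromosome 1, 27666061 to 27672218, ENSG00000126709), rose from 6.41 ± 0.576 FPKM with MEHP alone to 103 ± 10.3 FPKM (SD, n = 3). PSMB9, a subunit of the immunoproteasome that cuts peptides for antigen presentation (chromosome 6, 32844136 to 32859585), rose from 0.771 ± 0.126 to 9.36 ± 1.10 FPKM. CA9, a carbonic anhydrase and classical hypoxia target (chromosome 9, 35673856 to 35681159), rose from 2.09 ± 0.213 to 19.1 ± 3.27 FPKM. CEBPA, a transcription factor of hepatocyte identity, fell from 49.3 ± 2.78 to 32.9 ± 0.659 FPKM.

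Of 22 interferon-stimulated genes, 19 rose and 3 were not called (20 higher adjusted over the list alone; median log2 0.87, camera adjusted p = 9.5e-42; adjusted p = 2.6e-05 with an estimated correlation). IFI6 rose by 3.80 ± 0.10 on the log2 scale (limma adjusted p = 8.8e-09), IFI27, another interferon-induced gene, by 2.28 from 0.125 to 4.45 FPKM, and IFITM1, an antiviral membrane protein that overlaps its paralog IFITM2, by 1.99 from 5.20 to 23.7 FPKM. UBE2L6, the enzyme that attaches the ubiquitin-like protein ISG15, rose by 2.39 from 3.85 to 24.4 FPKM. Of 16 MHC class I presentation genes, 10 rose (15 higher adjusted over the list alone; median log2 0.71, camera adjusted p = 5.4e-28; adjusted p = 0.0014 with an estimated correlation). TAP1, the peptide transporter of the endoplasmic reticulum, rose from 6.67 ± 0.512 to 18.9 ± 0.716 FPKM, and HLA-E, a non-classical MHC class I gene with related family members, from 25.8 to 53.6 FPKM. PSMB9 and TAP1 overlap on opposite strands, so the split of reads between them is uncertain. Of 6 interferon-gamma and guanylate-binding genes, 4 rose, APOL1, ICAM1, IRF1 and APOL6 (4 adjusted over the list alone, median log2 0.88, camera adjusted p = 6.3e-10, adjusted p = 0.0027 with an estimated correlation). None of these 4 encodes a guanylate-binding protein. ICAM1 is also on the NF-kB list and IRF1 on the STAT3 feedback list, so the lists partly count the same genes.

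Of 17 NF-kB targets, 11 rose (13 higher adjusted over the list alone; median log2 0.79, camera adjusted p = 2.2e-24; adjusted p = 0.00018 with an estimated correlation). TNFAIP3, which restrains NF-kB signalling, rose from 6.18 ± 0.208 to 15.8 ± 0.115 FPKM, CCL20, a chemokine, from 29.2 ± 3.99 to 93.6 ± 4.18 FPKM, and TNIP1, a partner of TNFAIP3, from 13.9 to 24.8 FPKM. Of 16 acute phase genes, 6 rose and 2 fell (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.019, lost at an adjusted p = 0.20 with an estimated correlation and at 0.074 without MEHP replicate 3). The complement genes C1S and C3 rose from 0.969 to 3.92 and from 129 to 192 FPKM, and the fibrinogen genes FGG and FGA fell from 170 to 117 and from 226 to 176 FPKM. C1S and C3 overlap neighbouring genes on the same strand, so their levels are uncertain. Of 14 STAT3 feedback genes 3 rose, IRF1, PIM1 and CEBPD (5 higher adjusted over the list alone; median log2 0.23, camera adjusted p = 0.00011; adjusted p = 0.017 with an estimated correlation).

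Of 22 hypoxia targets, 20 rose and 2 were not called (22 higher adjusted over the list alone; median log2 0.73, camera adjusted p = 5.8e-38; adjusted p = 0.0050 with an estimated correlation). Of 19 glycolysis genes, 16 rose (19 higher adjusted over the list alone; median log2 0.56, camera adjusted p = 2.5e-30; adjusted p = 0.0050 with an estimated correlation). PFKFB4 and PFKFB3, which set the level of an activator of glycolysis, rose from 5.71 ± 0.503 to 18.6 ± 1.68 and from 4.44 ± 0.722 to 18.9 ± 2.91 FPKM. INSIG2, an anchor protein of sterol regulation that is on the hypoxia list, rose from 11.7 to 24.8 FPKM and ALDOC, an aldolase, from 18.5 to 33.8 FPKM. IGFBP1, a secreted binding protein of insulin-like growth factors, rose from 98.5 ± 9.48 to 539 ± 70.8 FPKM. Of 16 TGF-beta targets 4 rose, among them BHLHE40, CTGF and TGFB1 (6 higher and 1 lower adjusted over the list alone; median log2 0.11, camera adjusted p = 0.00020; adjusted p = 0.018 with an estimated correlation).

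Among the genes that fell were CPN2, a subunit of carboxypeptidase N (26.2 to 17.8 FPKM), and SULT2A1, a sulfotransferase of steroids and bile acids (44.6 to 31.2 FPKM). GSTA2, a glutathione transferase with close paralogs, fell from 2.98 to 1.57 FPKM. The 24 cholesterol genes had 0 called and the list's lower position (median log2 -0.14, camera adjusted p = 0.0062) was lost at an adjusted p = 0.29 with an estimated correlation. Of 24 PPAR-alpha targets, PLIN2 rose further, from 126 to 257 ± 15.7 FPKM, ANGPTL4, TXNIP and FABP1 also rose and SULT2A1 fell (6 higher and 1 lower adjusted over the list alone; median log2 0.08, camera adjusted p = 0.019, lost at an adjusted p = 0.14 with an estimated correlation). The other targets called higher with MEHP alone were not called here: CREB3L3 (log2 0.004), CPT1A (0.13), SLC25A20 (-0.06) and FADS2 (-0.08).

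In all, limma called 394 genes, 354 higher and 40 lower, 62 of them at least 2-fold and higher, and 20 lists, 8 of them also with an estimated correlation. Groups did not overlap in any of the 394 calls or in 21.3% of tested genes, where chance gives 10%. The count was 243 without MEHP replicate 1, 237 without MEHP replicate 3, 238 without M1 replicate 2 and 255 without M1 replicate 3, and 215 genes were called in each of the 6 fits that left out 1 library. TGFB1 was not called without MEHP replicate 1 (0.32) or 2 (0.34) or M1 replicate 1 (0.36), 2 (0.35) or 3 (0.37), nor with the length and GC trend removed (0.29). GSTA2 was not called without MEHP replicate 2 (-0.60) or 3 (-0.58) or M1 replicate 2 (-0.58) or 3 (-0.56), nor with no filter or its 6 libraries alone (-0.64 in each), nor without the 3 libraries that lay apart (-0.52). Leaving out M2 replicate 2, which is outside this comparison and enters only the shared variance, gave 805. Without the 3 libraries that lay apart it was 900 with 364 of the 394 among them, and with the length and GC trend removed 706 (520 higher, 186 lower).

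With M2 macrophages the hypoxia and glycolysis genes rose as well, a minority of the G1/S genes fell, and the interferon genes were not called as a group. CA9 rose from 2.09 ± 0.213 to 30.6 ± 7.36 FPKM (SD, n = 3). NDUFA4L2, a mitochondrial protein induced by low oxygen (chromosome 12, 57234903 to 57240715, overlapping SHMT2 on the other strand), rose from 0.723 ± 0.259 to 11.2 ± 2.84 FPKM. IGFBP1 rose from 98.5 ± 9.48 to 558 ± 145 FPKM. DNMT3B, a DNA methyltransferase, fell from 17.4 ± 0.429 to 10.9 ± 0.495 FPKM, and CEBPA from 49.3 ± 2.78 to 31.1 ± 0.732 FPKM.

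Of 22 hypoxia targets, 21 rose (22 higher adjusted over the list alone; median log2 0.94, camera adjusted p = 2.3e-36; adjusted p = 0.0050 with an estimated correlation), and 20 of the 22 rose with both macrophage types. Of 19 glycolysis genes, 17 rose (18 higher adjusted over the list alone; median log2 0.55, camera adjusted p = 9.2e-26; adjusted p = 0.0068 with an estimated correlation). The log2 fold changes were 3.33 ± 0.21 (SE) for CA9 (limma adjusted p = 1.1e-05), 1.94 ± 0.09 for PFKFB4 (limma adjusted p = 1.9e-06) and 2.14 ± 0.16 for PFKFB3 (limma adjusted p = 2.5e-05). SPAG4, a nuclear envelope protein, rose from 3.48 to 24.4 FPKM, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, from 1.67 to 7.83 FPKM. Of 16 TGF-beta targets, 4 rose (BHLHE40, CTGF and TGFB1 among them) and 2 fell (SMAD7 and ID3), with 7 higher and 2 lower adjusted over the list alone (median log2 0.17, camera adjusted p = 0.0011; adjusted p = 0.033 with an estimated correlation).

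Of 29 G1/S genes, 6 fell and 23 were not called (10 lower adjusted over the list alone; median log2 -0.22, camera adjusted p = 5.3e-06; adjusted p = 0.018 with an estimated correlation). UHRF1, a partner of DNA methylation at replication, fell from 54.1 ± 1.98 to 38.9 ± 3.31 FPKM, CDC6, which helps prepare replication origins, from 28.5 to 22.1 FPKM, and PCNA, the sliding clamp of DNA polymerase, from 346 to 285 FPKM. Of 27 p53 targets 3 fell, AEN, CDKN1A and BTG2 (7 lower and 1 higher adjusted over the list alone; median log2 -0.29, camera adjusted p = 0.00041; adjusted p = 0.042 with an estimated correlation). Of 32 G2/M genes, 3 fell, AURKA, KIF20A and CCNB1 (8 lower adjusted over the list alone; median log2 -0.21, camera adjusted p = 0.00011, lost at an adjusted p = 0.16 with an estimated correlation). Of 24 cholesterol genes, 4 fell (10 lower adjusted over the list alone; median log2 -0.20, camera adjusted p = 6.5e-05, lost at an adjusted p = 0.14 with an estimated correlation). Among them ACAT2, an acetyl-CoA acetyltransferase, fell from 49.2 to 40.2 FPKM and LSS from 43.3 to 32.7 FPKM. Of 16 heat shock genes 3 fell, HSPA1B, DNAJB1 and HSPH1 (6 lower adjusted over the list alone; camera adjusted p = 0.00014, lost at an adjusted p = 0.082 with an estimated correlation).

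Of 17 NF-kB targets, 5 rose (7 higher and 1 lower adjusted over the list alone; median log2 0.20, camera adjusted p = 5.5e-06; adjusted p = 0.0068 with an estimated correlation). TNIP1 rose from 13.9 to 24.6 FPKM, IER3, an early response gene, from 59.4 to 118 FPKM, and CCL20 from 29.2 to 70.3 FPKM. Of 22 interferon-stimulated genes 2 rose, the overlapping paralogs IFITM1 (5.20 to 8.71 FPKM) and IFITM2 (28.5 to 47.2 FPKM), and the list was not called (camera adjusted p = 0.35). IFI6 was at 7.94 ± 0.568 FPKM. Of 16 acute phase genes 3 rose, among them ITIH3 (11.3 to 19.3 FPKM) and LRG1 (12.6 to 16.6 FPKM), both secreted by the liver, and 1 fell, FGG (170 to 134 FPKM). That list (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.024) lost its call at an adjusted p = 0.21 with an estimated correlation, and at 0.081 without MEHP replicate 3 and 0.14 without M2 replicate 2. Of 24 PPAR-alpha targets 4 rose, including PLIN2 (126 to 269 ± 44.8 FPKM), and 1 fell (8 higher and 4 lower adjusted over the list alone; median log2 0.13, camera adjusted p = 0.024). That call was lost at an adjusted p = 0.15 with an estimated correlation, at 0.068 without M2 replicate 1 and at 0.056 without M2 replicate 3. The targets CREB3L3 (log2 0.14), CPT1A (0.18), SLC25A20 (-0.18) and FADS2 (-0.12), called higher with MEHP alone, were not called with M2 against MEHP. MRAS, a Ras-related protein, fell from 5.65 to 3.07 FPKM, GPAM, the first enzyme of glycerolipid synthesis, from 18.7 to 11.8 FPKM, and BHLHA15, a transcription factor of secretory cells, from 5.35 to 2.89 FPKM.

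In all, limma called 703 genes, 467 higher and 236 lower, 75 of them at least 2-fold, and 21 lists, 6 of them also with an estimated correlation. Groups did not overlap in any of the 703 calls or in 19.8% of tested genes, where chance gives 10%. The count was 337 without MEHP replicate 1, 315 without MEHP replicate 3 and 1167 without M2 replicate 2, and it was 157 when only the 6 libraries of the comparison were fitted. In that 6-library fit UHRF1, CDC6, PCNA, ACAT2, LSS, AURKA, KIF20A, CCNB1, GPAM, BHLHA15, LRG1, ITGB2, IFITM1, IFITM2, TGFB1, SMAD7, ID3, AEN, CDKN1A, BTG2, HSPA1B, DNAJB1, HSPH1 and FGG were not called. Leaving out MEHP replicate 1 or 3 ended the calls of CDC6 (-0.33, -0.34), PCNA (-0.30, -0.30), AURKA (-0.24, -0.24), KIF20A (-0.23, -0.21), CCNB1 (-0.24, -0.24), GPAM (-0.58, -0.62), BHLHA15 (-0.72, -0.78) and IFITM2 (0.61, 0.66). MEHP replicate 1 ended that of LSS (-0.35) and MEHP replicate 3 those of ACAT2 (-0.27) and LRG1 (0.33). MEHP replicate 2 ended those of PCNA (-0.25), AURKA (-0.25), KIF20A (-0.22), CCNB1 (-0.24) and BHLHA15 (-0.73), M2 replicate 1 those of PCNA (-0.28) and KIF20A (-0.19), and M2 replicate 3 those of KIF20A (-0.21) and CCNB1 (-0.22). Among members named after their values were seen, ID3, CDKN1A and FGG were not called without MEHP replicate 1 (-0.40, -0.32, -0.32), 2 (-0.36, -0.29, -0.33) or 3 (-0.38, -0.32, -0.38). BTG2, DNAJB1 and HSPH1 were not called without MEHP replicate 1 (-0.31, -0.24, -0.50) or 3 (-0.35, -0.27, -0.52). AEN was not called without MEHP replicate 1 (-0.31) nor SMAD7 without MEHP replicate 3 (-0.32). M2 replicate 1 ended the calls of ID3 (-0.35), CDKN1A (-0.30) and HSPH1 (-0.60), M2 replicate 2 that of BTG2 (-0.31), and M2 replicate 3 those of ID3 (-0.28) and BTG2 (-0.33). Leaving out any 1 DMSO or M1 library, which enter only the shared variance, also ended the calls of ID3 (-0.38), HSPH1 (-0.56) and FGG (-0.34). Any 1 DMSO library ended those of BTG2 (-0.36), AURKA (-0.24), KIF20A (-0.22) and CCNB1 (-0.24). M1 replicate 1 ended that of KIF20A (-0.22), M1 replicate 2 those of BTG2 (-0.36) and AURKA (-0.24), and M1 replicate 3 those of AURKA (-0.24), KIF20A (-0.22) and CCNB1 (-0.24). Without the 3 libraries that lay apart, 1590 genes were called, 661 of the 703 among them, with 22 hypoxia targets higher and 10 G1/S genes lower. With the length and GC trend removed there were 1419 (712 higher, 707 lower), so that the excess of higher genes was not kept, and BHLHA15 was not called (-0.87).

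**Figure D3:**
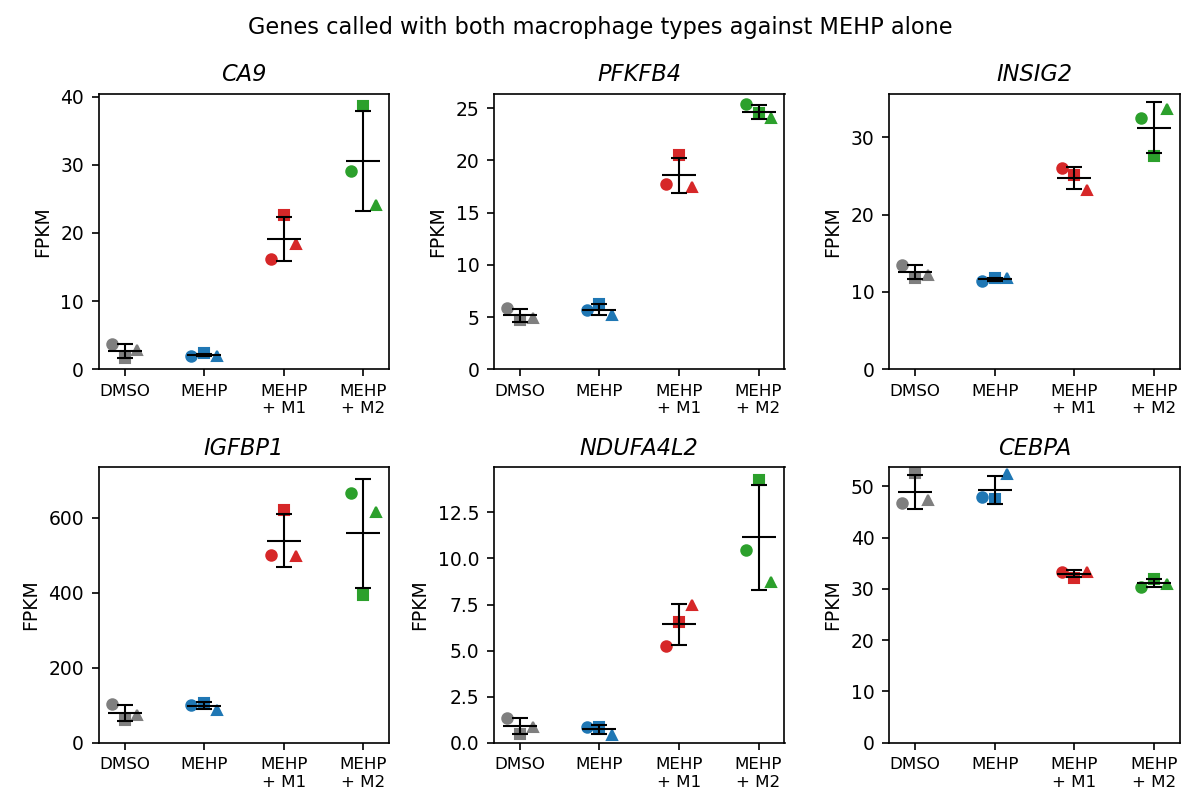
FPKM (vertical axis, linear from 0) of 6 genes called with both macrophage types against MEHP alone, with 1 point per library in each of the 4 groups (horizontal axis) and black bars for the mean and SD of 3 libraries. CA9 stands at 2.09 with MEHP alone, 19.1 with M1 and 30.6 with M2 macrophages, while CEBPA stands at 49.3, 32.9 and 31.1.

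Many genes were called in the same direction with both macrophage types against MEHP alone. Genes called higher with both numbered 269 and genes called lower with both 30. In 50 simulations of unchanged groups that share the MEHP libraries these counts were 0 and 0. Unchanged groups give few calls in either comparison, so these simulated counts cannot show whether the responses are shared. Independent lists of the same lengths give 13.6 and 0.776, which leaves the shared MEHP libraries out of account. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.737 (simulated mean 0.509, range -0.306 to 0.935) with a covariance of 0.0433 (simulated mean 0.0172, range -0.00947 to 0.102), a difference of 0.0261. Both values lie inside the simulated ranges. The 3 MEHP libraries cannot be split into parts of 2, so part of the excess may come from the shared controls.

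The direct comparison of M1 with M2 macrophages was dominated by interferon genes. IFI6 was at 103 ± 10.3 FPKM with M1 and 7.94 ± 0.568 FPKM with M2 macrophages (SD, n = 3), a log2 difference of 3.53 ± 0.10 (SE; limma adjusted p = 2.0e-08). ISG15, a ubiquitin-like interferon-induced protein, was at 143 ± 18.3 against 43.1 ± 15.2 FPKM, and PSMB9 at 9.36 ± 1.10 against 0.737 ± 0.0226 FPKM.

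Of 22 interferon-stimulated genes, 16 were higher with M1 (20 adjusted over the list alone; median log2 0.83, camera adjusted p = 6.5e-59; adjusted p = 1.3e-05 with an estimated correlation). Of 16 MHC class I presentation genes, 8 were higher (14 adjusted over the list alone; median log2 0.69, camera adjusted p = 1.4e-38; adjusted p = 0.00065 with an estimated correlation), including TAP1 (18.9 against 5.63 FPKM) and NLRC5, the activator of MHC class I transcription (3.86 against 1.17 FPKM). Of 6 interferon-gamma and guanylate-binding genes, 4 were higher (5 adjusted over the list alone; median log2 0.69, camera adjusted p = 4.5e-14; adjusted p = 0.00094 with an estimated correlation), including APOL1 (4.06 against 1.5 FPKM) and APOL6 (3.27 against 0.982 FPKM). Of 17 NF-kB targets, 5 were higher (10 adjusted over the list alone; median log2 0.30, camera adjusted p = 4.3e-17; adjusted p = 0.00054 with an estimated correlation), including TNFAIP3 (15.8 against 8.02 FPKM), the adhesion molecule ICAM1 (32.5 against 19.4 FPKM) and the ribonuclease ZC3H12A (13.1 against 6.65 FPKM). ICAM1 is on both the NF-kB and the interferon-gamma list. UBE2L6, IFI27, PARP14 and C1S were also higher with M1, by 2.45, 2.32, 1.27 and 1.34 on the log2 scale. C3 was at 192 against 147 FPKM without passing the main test (limma adjusted p = 0.075). It was called without M1 replicate 1 (0.45) and with the length and GC trend removed (0.36).

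Lower with M1 than with M2 were ANKRD37, a hypoxia-induced gene that overlaps UFSP2 (3.21 ± 0.157 against 5.32 ± 0.596 FPKM), MIXL1, a homeobox gene (14.5 ± 0.789 against 20.8 ± 2.01 FPKM), and a pseudogene, CBX3P9, named after its values were seen. Of 22 hypoxia targets 1 was lower with M1, ANKRD37 (4 lower adjusted over the list alone), and 21 of 22 lay below 0 (median log2 -0.21, camera adjusted p = 3.2e-11, lost at an adjusted p = 0.076 with an estimated correlation). The 70 ribosomal protein genes had 0 called (median log2 -0.08, camera adjusted p = 0.00062, lost at an adjusted p = 0.69 with an estimated correlation), and their median turned to 0.04 without the 3 libraries that lay apart and to 0.09 without M2 replicate 2, and the call was lost without M1 replicate 2 (median -0.04).

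In all, limma called 50 genes, 47 higher and 3 lower with M1, 22 of them at least 2-fold, and 15 lists, 4 of them also with an estimated correlation. Groups did not overlap in any of the 50 calls or in 8.77% of tested genes, where chance gives 10%. Of the 47 higher genes, 42 were also called higher with M1 against MEHP, and 5 of these 42 were called with M2 against MEHP. Both M1 comparisons use the same M1 libraries, so their agreement is partly built in. On a fixed interferon, MHC class I, guanylate-binding or NF-kB list were 32 of the 47. The count was 78 without M2 replicate 2, 21 when only the 6 libraries of the comparison were fitted (with ISG15, ANKRD37, MIXL1, ICAM1, ZC3H12A, APOL6 and CBX3P9 no longer called), and 81 without the 3 libraries that lay apart, 48 of the 50 among them. ANKRD37 was not called without M1 replicate 1 (-0.57) or 2 (-0.57), and MIXL1 was not called without M1 replicate 1 (-0.49), 2 (-0.53) or 3 (-0.45) or M2 replicate 1 (-0.47) or 3 (-0.44). MIXL1 was also not called without DMSO replicate 2 or 3 or MEHP replicate 1, which enter only the shared variance (-0.49 in each), nor with the length and GC trend removed (-0.47). CBX3P9 lost its call without any 1 of the 6 libraries of the comparison (-0.51 to -0.57). It also lost it without DMSO replicate 1 or any 1 MEHP library, which likewise enter only the shared variance (-0.55). The fits without the 3 libraries that lay apart (-0.59), with the length and GC trend removed (-0.46), with voom (-0.88) and with no filter (-0.55) did not call it either.

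**Figure D4:**
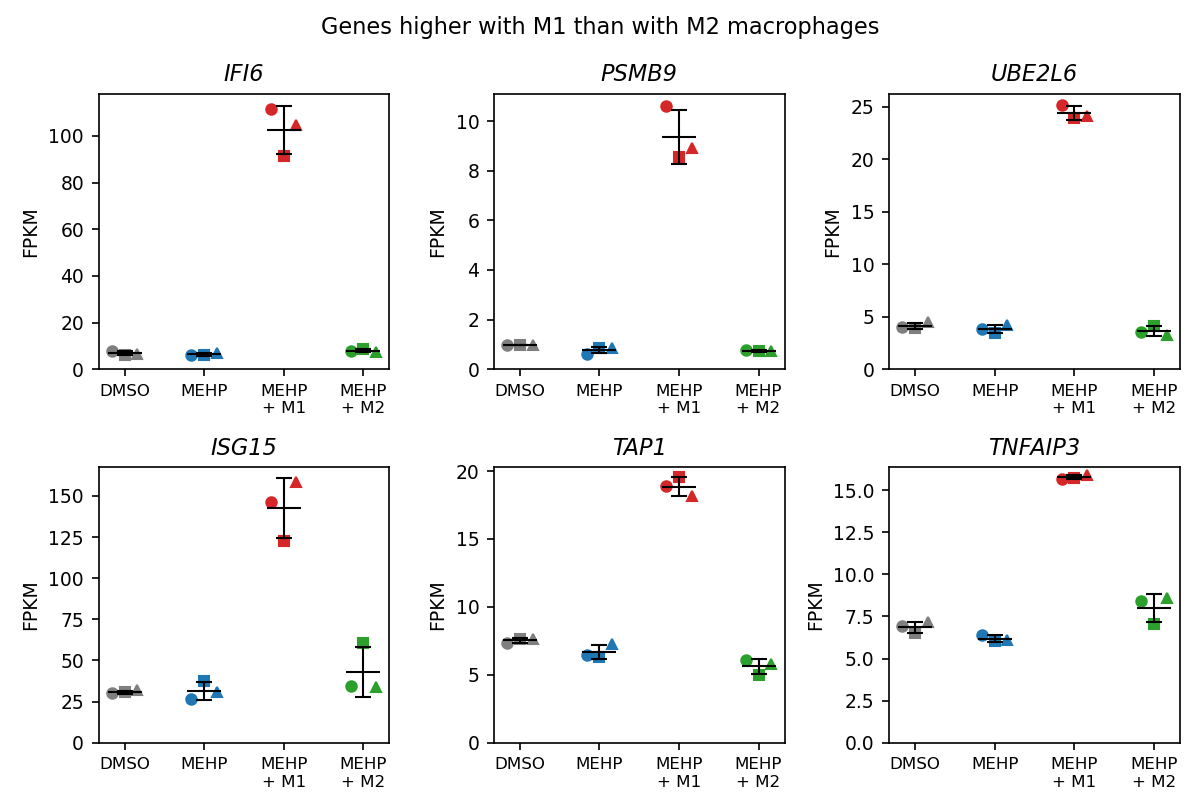
FPKM (vertical axis, linear from 0) of 6 genes higher with M1 than with M2 macrophages, with 1 point per library in each of the 4 groups (horizontal axis) and black bars for the mean and SD of 3 libraries. IFI6 stands at 103 with M1 macrophages and between 6.41 and 7.94 in the other 3 groups, and UBE2L6 at 24.4 against 3.65 to 4.14.

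Against DMSO, MEHP with M1 macrophages changed 628 genes (484 higher, 144 lower) and MEHP with M2 macrophages 1293 (728 higher, 565 lower). These comparisons share the DMSO libraries with the first one, so agreement in direction with it is partly built in. All 11 genes called with MEHP alone were called in the same direction in both, including CREB3L3 (log2 1.63 and 1.76), CPT1A (0.99 and 1.04) and PLIN2 (2.23 and 2.28). Of the 32 G2/M genes 5 fell with M1 and 9 with M2 macrophages, and of the 29 G1/S genes 1 and 12. These counts do not show a difference between the macrophage types. In the direct comparison of M1 with M2, 0 members of either list were called, and the G1/S list (median log2 0.105) was called with the preset correlation only. In the comparisons with DMSO, groups did not overlap in 40.4% and 35.2% of tested genes, where chance gives 10%. The first count was 352 without DMSO replicate 2, 361 without DMSO replicate 3, 365 without M1 replicate 2, 366 without M1 replicate 3 and 1692 without M2 replicate 2, which is outside the comparison. It was 2070 with its own 6 libraries, 1879 without the 3 libraries that lay apart, and 1162 (714 higher, 448 lower) with the length and GC trend removed. The second count was 735, 588 and 593 without DMSO replicate 1, 2 or 3, 331 with its own 6 libraries, 2624 without the 3 that lay apart, and 2455 (1142 higher, 1313 lower) with the trend removed, where the majority turned.

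Markers of other cells held few reads in every group, and macrophage markers held more in the co-cultures than with MEHP alone, a difference that was not tested. The 34 macrophage and leukocyte markers nearly absent from the control held 93 reads in the 3 DMSO libraries (22 to 40 each), 90 in the MEHP libraries (27 to 34), 170 in the M1 libraries (38 to 66) and 181 in the M2 libraries (57 to 63). The gain was uneven, as the genes picked after their values were seen show: ITGAX went from 13 reads with MEHP to 35 with M1 and 69 with M2 macrophages and CTSS from 11 to 33 and 8, while PTPRC, TYROBP, CD53, CYBB, PLEK, LCP2, C1QA and MS4A7 together held 4 reads with DMSO and 3 in each other group. ITGB2, an integrin of leukocytes that HepG2 libraries held at 2.33 FPKM under DMSO, rose from 2.19 ± 0.147 FPKM with MEHP to 3.63 ± 0.330 with M1 and 3.67 ± 0.461 with M2 macrophages (limma adjusted p = 0.0058 and 0.0045), the M2 call being lost with the 6 libraries of that comparison alone (0.55). LYZ, lysozyme, was high in all groups (259 to 332 FPKM) and not called in any of the 4 main comparisons. It was called with M2 without M2 replicate 2 (0.37), with M1 when only those 6 libraries were fitted or M2 replicate 2 was left out (0.36 in each), and with M1 (0.32) and M2 (0.33) without the 3 libraries that lay apart. The nearly absent M2 macrophage markers held 33 reads in the DMSO, 21 in the MEHP, 33 in the M1 and 59 in the M2 libraries, and the M1 macrophage markers 14, 14, 17 and 17. Per library, lymphocyte markers held 0 to 9, fibroblast markers 4 to 9 and endothelial markers 7 to 15. The list of MHC class II genes had 1 tested member.

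**Figure D5:**
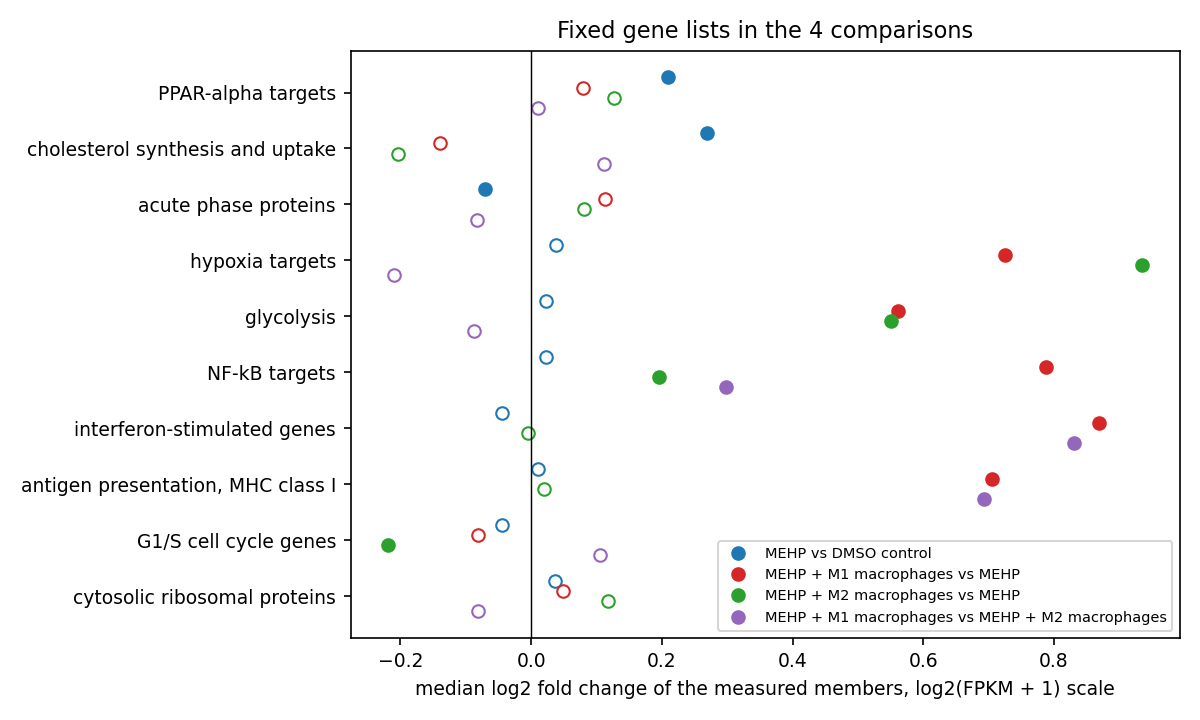
Median log2 fold change of the measured members (horizontal axis, log2(FPKM + 1) scale) of 10 fixed gene lists (vertical axis) in the 4 main comparisons (colours). Filled points were called by camera with both the preset and an estimated correlation and open points were not; hypoxia targets stand at 0.73 and 0.94 with M1 and M2 macrophages, interferon-stimulated genes at 0.87 with M1 against MEHP and 0.83 with M1 against M2.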

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

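The direct test of M1 against M2 macrophages was the only source of results marked for a closer look, because single outlying samples were not tested in groups of 3. The rise of hypoxia targets over MEHP alone and the 3 libraries that lay apart are examined below too, though that test did not mark them. The reads of macrophage markers in 2 of the patterns below, the median with 1 library left out, the library size, the position between groups and the splits of libraries are tests chosen only after the result was seen. The direct test called 50 genes. Genes that differed were IFI6 (3.53 on the log2 scale), PSMB9 (2.57), UBE2L6 (2.45), IFI27 (2.32), ISG15 (1.75), TAP1 (1.59), C1S (1.34), PARP14 (1.27), NLRC5 (1.17), APOL6 (1.13), APOL1 (1.02), TNFAIP3 (0.898), ZC3H12A (0.889), ICAM1 (0.723), MIXL1 (-0.491) and ANKRD37 (-0.584). Lists that differed had median log2 differences of 0.831 (interferon-stimulated genes), 0.693 (MHC class I presentation), 0.298 (NF-kB targets), 0.692 (interferon-gamma and guanylate-binding genes), -0.209 (hypoxia targets), -0.0819 (ribosomal proteins), 0.105 (G1/S genes), 0.112 (cholesterol synthesis), -0.0880 (glycolysis), 0.132 (ER chaperones), 0.114 (p53 targets), -0.0670 (hepatocyte secreted proteins), -0.0741 (bile acid genes), 0.0878 (heat shock proteins) and -0.0623 (nuclear OXPHOS subunits).

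Interferon genes stood higher with M1 than with M2 macrophages. Reads from macrophages are an unlikely cause of its size, since the 34 fixed macrophage and leukocyte markers nearly absent from the control gained 80 reads over MEHP in the M1 libraries (90 to 170), 0.144% of the 55745 reads gained by the interferon list, and held 181 reads in the M2 libraries. No single library decided it, as the median of all 22 members of the list stayed at 97% or more of its value in the 6 fits with 1 M1 or M2 library left out (highest camera adjusted p = 2.31e-38), with 14 to 16 of the 16 called members still called, and without the 3 libraries that lay apart the list median was 106% of that with all. A response of the HepG2 cells to a signal from M1 macrophages is a hypothesis that these tests leave open, and a carry-over of polarising interferon with the macrophages could give the same pattern.

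Hypoxia targets stood higher with either macrophage type. The same markers gained 171 reads in the 6 co-culture libraries, 0.0807% of those gained by the hypoxia list, and the lower of the 2 list medians became 107% of its value when the 3 libraries that lay apart were left out and 102% when the trend on gene length and GC content was removed. The ATF4 list median was -1.04% of the hypoxia median with M1 and 0.424% with M2 macrophages, which argues against a shift of the whole list of nutrient stress genes. Of its 32 members 5 (DDIT4, STC2, VEGFA, SHMT2 and GPT2) were higher with either type, while YARS (-0.23) and AARS (-0.25) were lower with M2. VEGFA is itself a hypoxia target, so it cannot tell nutrient stress from hypoxia, and SHMT2 overlaps the strongly raised NDUFA4L2. A shift of a part of the list stays open. Oxygen use by more cells in a well and a signal from macrophages remain possible, and neither was measured. A trace of macrophage RNA in the libraries also remains possible, as the markers rose slightly, but that rise was uneven over genes and does not settle it. The marker gain of 171 reads beside 211822 for the hypoxia list argues against macrophage RNA as the cause of the size of the hypoxia rise.

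MEHP replicate 2, M1 replicate 3 and M2 replicate 2 lay apart from their groups. Their deviations followed gene length or GC content with a Spearman rho of up to 0.566, which fits a technical difference in library preparation or RNA quality. Library size is an unlikely cause, as 3 of the 3 totals lay inside the range of the other 9, and so is a swapped label, as the highest position on the line to another group was 0.167 (1 being that group). What differed in their handling stays open.

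With 3 against 3 libraries there are 10 splits, so the share of splits with a count as large is never under 0.1. Every other split puts libraries of both groups on each side, so a difference between the groups adds to the spread and shrinks the contrast. Low gene counts in the other splits therefore follow from any group difference, whatever its cause. Lists called in them can come from the part of the difference that they keep. For genes, 1 split, the real one, reached the count in each comparison: 11 against 0 at most in the others for MEHP against DMSO, 394 against 0 for M1 against MEHP, 703 against 1 for M2 against MEHP, 50 against 0 for M1 against M2, 628 against 0 for M1 against DMSO and 1293 against 1 for M2 against DMSO. For lists, 2 splits reached 12 for MEHP against DMSO (highest other 12), and 1 split, the real one, reached 20 (highest other 16), 21 (highest other 8) and 15 (highest other 10) in the other main comparisons.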

How the results depend on the processing

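The main choices were made before the data were examined; the fit without the 3 libraries that lay apart and the removal of a length and GC trend were added after. The cause of the changes below was not tested. Ranges with 1 library left out are over the 6 libraries of the comparison. No called gene turned its sign under any alternative. Genes called for MEHP against DMSO (11) became 17 with no filter, 6 with a replicate block, 32 without the 3 libraries, 28 with the length and GC trend removed, 2 with the 2-fold limit and 4 to 7 with 1 library left out. For M1 against MEHP (394) they became 900 without the 3, 706 with the trend removed, 62 with the 2-fold limit and 237 to 308 with 1 library left out. For M2 against MEHP (703) they became 157 with its 6 libraries alone, 1590 without the 3, 1419 with the trend removed, 75 with the 2-fold limit and 315 to 1167 with 1 library left out. For M1 against M2 (50) they became 21 with its 6 libraries alone, 81 without the 3, 22 with the 2-fold limit and 40 to 78 with 1 library left out. For M1 against DMSO (628) they became 2070 with its 6 libraries alone, 1879 without the 3, 1162 with the trend removed, 78 with the 2-fold limit and 352 to 501 with 1 library left out. For M2 against DMSO (1293) they became 331 with its 6 libraries alone, 2624 without the 3, 2455 with the trend removed, 93 with the 2-fold limit and 588 to 1880 with 1 library left out. Leaving out 1 of the 6 libraries outside the comparison gave, in the same order, 9 to 29, 309 to 805, 506 to 605, 46 to 49, 530 to 1692 and 926 to 1205, and the 29, 805 and 1692 were without M2 replicate 2. Lists called in the 4 main comparisons (12, 20, 21 and 15) fell to 5, 8, 6 and 4 with an estimated correlation, and ranged over 11 to 14, 19 to 24, 17 to 24 and 10 to 14 with 1 library left out. Genes called in the same direction with both macrophage types (299) became 684 without the 3 and 557 with the trend removed. Some small list medians changed sign: ribosomal proteins in M2 against MEHP (0.118) ranged from -0.0375 to 0.263 with 1 library left out, nuclear OXPHOS subunits in M1 against M2 (-0.0623) were 0.0184 without the 3 and -0.164 to 0.0585 with 1 left out, and ribosomal proteins in M1 against M2 (-0.0819) were 0.0409 without the 3 and -0.214 to 0.0864 with 1 left out. No pairing by replicate number held over all groups: residuals of libraries with the same number correlated at -0.446 to 0.66, and 4 of 12 libraries correlated best with their own number. MEHP and M2 libraries of the same number did correlate (0.389, 0.66 and 0.315), where replicate 2 lay apart in both groups, so pairing of these is not excluded. The replicate block ended the M2 against MEHP calls of AURKA (-0.24), KIF20A (-0.22) and CCNB1 (-0.24), all 3 of the called G2/M genes, and of FGG (-0.34), the MEHP against DMSO calls of FGA, FGB, DHCR7, FDFT1 and FADS2, the M1 against MEHP call of GSTA2 (-0.64) and the M1 against M2 calls of MIXL1 (-0.49) and CBX3P9 (-0.55). Of the M2 against MEHP genes named, no filter ended the calls of BHLHA15, GPAM, PCNA, CCNB1, IFITM2, ID3, BTG2, HSPH1 and FGG (the last 4 also with the 0.1 filter), median-ratio scaling those of KIF20A, ID3 and FGG, quantile normalization those of AURKA, HSPH1 and FGG, and voom that of KIF20A. Array weights did not converge and were not used.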

Other observations

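Other lists were called by camera with the preset correlation only, each here with its median log2 fold change and its adjusted p with an estimated correlation. For MEHP against DMSO these were mitochondrial fatty acid oxidation (0.10, adjusted p = 0.14), ATF4 targets (0.06, 0.11), ER chaperones (0.08, 0.21), p53 targets (-0.07, 0.11), mitochondrially encoded proteins (0.18, 0.49) and histones (-0.12, 0.24). For M1 against MEHP these were complement (0.08, 0.10), heat shock proteins (-0.13, 0.12), p53 targets (-0.12, 0.12), G1/S genes (-0.08, 0.062), G2/M genes (-0.15, 0.12), gluconeogenesis (0.20, 0.064), drug metabolism (-0.11, 0.10), Wnt targets (-0.14, 0.10) and immediate early genes (0.24, 0.076). For M2 against MEHP these were fatty acid synthesis (-0.20, 0.12), hepatocyte secreted proteins (0.15, 0.38), STAT3 feedback genes (0.15, 0.076), ER chaperones (-0.15, 0.24), gluconeogenesis (0.07, 0.12), ribosomal proteins (0.12, 0.69), drug metabolism (-0.29, 0.091), liver transcription factors (-0.13, 0.23), Wnt targets (-0.10, 0.12) and immediate early genes (0.23, 0.11). With the preset correlation too, some calls rested on 1 library (adjusted p without it in brackets). For MEHP against DMSO these were mitochondrial fatty acid oxidation (without MEHP replicate 2, 0.058), mitochondrially encoded proteins (without MEHP replicate 2, 0.063), ER chaperones (without MEHP replicate 1, 0.12) and histones (without DMSO replicate 2, 0.068; without MEHP replicate 1, 0.30, or 3, 0.095). For M1 against MEHP it was Wnt targets (without M1 replicate 1, 0.078). For M2 against MEHP these were STAT3 feedback genes (without M2 replicate 3, 0.053), ribosomal proteins (without M2 replicate 2, 0.45), ER chaperones (without M2 replicate 2, 0.11), liver transcription factors (without MEHP replicate 1, 0.064, or M2 replicate 2, 0.20) and hepatocyte secreted proteins (without MEHP replicate 3, 0.057, or M2 replicate 2, 0.14). They were also gluconeogenesis (without MEHP replicate 2, 0.063, or M2 replicate 1, 0.059, or 3, 0.070) and Wnt targets (without MEHP replicate 3, 0.054, or M2 replicate 1, 0.067, or 3, 0.086). The 24 peroxisomal proteins had 0 called members with MEHP (median log2 -0.0021, camera adjusted p = 0.80).

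For M1 against M2 macrophages the lists called with the preset correlation only, with their adjusted p with an estimated correlation, were G1/S genes (0.076), p53 targets (0.11), ER chaperones (0.21), heat shock proteins (0.23), cholesterol synthesis (0.25), bile acid genes (0.27), glycolysis (0.33), hepatocyte secreted proteins (0.38) and nuclear OXPHOS subunits (0.63). All of these but G1/S genes lost the preset call without 1 or more of the 6 libraries (adjusted p in brackets). They were p53 targets (without M1 replicate 1, 0.060, or M2 replicate 3, 0.13), ER chaperones (without M1 replicate 1, 0.087, or M2 replicate 2, 0.13), cholesterol synthesis (without M2 replicate 2, 0.080), bile acid genes (without M2 replicate 2, 0.48) and glycolysis (without M1 replicate 1, 0.097, or M2 replicate 1, 0.24). They were also nuclear OXPHOS subunits (without M1 replicate 2, 0.36, or M2 replicate 2, 0.49), hepatocyte secreted proteins (without M1 replicate 1, 0.087, or 2, 0.068, or M2 replicate 2, 0.53) and heat shock proteins (without M1 replicate 1, 0.15, or 3, 0.053, or M2 replicate 1, 0.067, or 2, 0.11).

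The 32 ATF4 targets were not called as a list with M1 or M2 macrophages against MEHP (camera adjusted p = 0.236 and 0.461). The members DDIT4 (0.74 with M1 and 1.03 with M2), STC2 (0.51 and 0.65), VEGFA (0.57 and 0.77, also a hypoxia target), SHMT2 (0.36 and 0.36) and GPT2 (0.33 and 0.35) were called higher with both, SHMT2 and GPT2 not with the 6 libraries of M2 against MEHP alone. YARS (-0.23) and AARS (-0.25) were called lower with M2, neither of them with those 6 libraries alone. YARS lost its call without MEHP replicate 1 (-0.23), 2 (-0.23) or 3 (-0.25) or M2 replicate 1 (-0.23). AARS lost it without MEHP replicate 1 (-0.22), 2 (-0.26) or 3 (-0.27), M2 replicate 3 (-0.21) or any 1 DMSO or M1 library (-0.25), and with a weaker filter, median-ratio scaling (-0.23) or the replicate block. These members were named after their values were seen.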
